A study of Mus musculus with 28 samples.

How the data were processed

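The study measured messenger RNA in intestinal epithelium from mice that the series design text calls adult, by bulk RNA sequencing, in 28 libraries from 4 segments (jejunum, ileum, cecum and colon). Per the labels' protocols, epithelium was released with EDTA 30 days after tamoxifen from mice that carry a floxed Satb2 gene with an inducible Cre recombinase under the villin promoter (Vil-CreER;Satb2f/f, here KO) or the floxed gene alone (Satb2f/f, here WT). The labels give 3 WT and 4 KO libraries for each segment and number them from 1 upward in each group. They do not say whether the libraries of a group came from separate animals, or whether the same number marks the same animal in different segments. The p-values given here therefore measure only the spread among these libraries. The labels give no sequencing batch, date, sex or cage.

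Libraries were non-directional mRNA libraries made with the NEBNext Ultra RNA kit and were sequenced as read pairs of 150 nt, per the labels' protocols. Trim Galore, STAR, featureCounts and DESeq2, with the mouse build GRCm38, are named in the submitters' processing notes without versions. Per the series design text, featureCounts assigned reads to genes without regard to strand, so reads from a gene and from an antisense or overlapping partner cannot be told apart. The gene annotation is not stated. The authors deposited a table of raw counts per gene with 24015 genes. Of its gene symbols, 22709 occur in GENCODE M21 and 22508 in the RefSeq genes of GRCm38. The deposited normalized table holds a signal for 24014 genes, which was checked to be each raw count divided by 1 factor per library. Those factors matched median-of-ratios size factors computed over the 28 libraries of the count table (largest relative difference 4.96e-11). Multiplying the factors back gave whole reads for 100% of values, within a tolerance of 0.001. No mitochondrially encoded gene is in the count table. No 2 libraries had identical counts.

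Comparisons were made on the raw counts with edgeR 4.0.16 in R 4.3.3. Each comparison was fitted to its own 6 or 7 libraries. Genes were kept by filterByExpr with a minimum count of 10, library sizes were scaled by TMM, and genes were tested with the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes kept. A gene passed the test at an adjusted p under 0.05. Fold changes are on the log2 scale with standard errors derived from the test statistic, and levels are CPM (counts scaled to a common library total) as mean and SD over a group's libraries. Satb2 in all libraries was computed on 1 scale over the 28 libraries. KO was compared with WT in each segment. WT ileum was compared with WT colon, WT jejunum with WT ileum, WT cecum with WT colon, and KO colon with WT ileum. Whether the knockout effect differed between colon and each other segment was tested as a difference of log2 fold changes in 1 fit of all 28 libraries.

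Where every library of a group counted 0 reads of a gene, the fold is given as at least the ratio to a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its 95% counting interval. These intervals and floors cover counting error only. Members of near-identical gene families (Defa, Reg3, Gsdmc, Cyp, Ces and Ugt genes) are given with the limit that reads may have been split between copies.

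Before the data were examined, 31 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. Lists cover absorption, transport, cell types of the epithelium, transcription factors, metabolism, interferon responses, stress and other tissues. Of these, 30 had members in the count table. Each list was compared with all other tested genes by camera in limma 3.58.1 with a correlation between genes estimated from the residuals, and again with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Members past the gene test were counted, and counted again after adjustment over the list alone. Named genes were Satb2, then for each KO comparison the 10 genes with the largest rise and the 10 with the largest fall among genes past the test that had a mean of at least 10 CPM in the higher group and no overlap between groups. For the regional comparisons and the differences of effects the number was 5 in each direction. Up to 4 members of each list past the test, by smallest p, and up to 2 not past it could also be named. Unnamed gene models and immunoglobulin or T cell receptor segments were left out, and the text names fewer genes than the rule allows.

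A small-intestine index placed each KO colon and KO cecum library between WT of its own segment (0) and WT ileum (1). It is the mean over signature genes of the library's log2 CPM, with a prior count of 2, signed by the direction of each gene and then set to 0 and 1 at the 2 WT means. Signature genes passed the test with an absolute log2 fold change of at least 2 between WT ileum and the WT libraries of the other large-intestine segment, so that the libraries that define 0 did not select the genes. KO and WT libraries were compared by an exact permutation test over all 35 splits of the 7 libraries, two-sided, whose smallest possible p is 0.0286.

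The steps were tested on simulated data drawn from the means, spreads and totals of the real libraries, with 100 genes changed 2-fold and 100 changed 4-fold. The gene test recovered 46% and 86% of them in the design of the colon comparison (11230 genes), 35% and 94% in cecum (10980 genes), 9% and 82% in ileum (10157 genes) and 29% and 85% in jejunum (10217 genes). The shares were 26% and 85% for WT ileum against WT colon (11205 genes), 11% and 87% for WT jejunum against WT ileum (10508 genes), 53% and 89% for WT cecum against WT colon (11133 genes) and 20% and 88% for KO colon against WT ileum (10849 genes). For differences of effects they were 6% and 55% against cecum (12013 genes), 4% and 46% against ileum (11989 genes) and 3% and 59% against jejunum (12015 genes). Unchanged genes made up between 0% and 9.26% of the calls. A list shifted 2-fold passed the list test in the designs of all 4 segments and no other list did. The simulated genes were drawn independently of one another. The list result therefore does not show how often a shifted list passes where its genes vary together, as in real libraries. The index of simulated libraries came out at 0.49 for colon and 0.479 for cecum where 0.5 was built in. For an index of 0 the KO means were the WT means plus a small constant that WT did not get, which lifts genes near 0. The index then came out at 0.0105 (exact p = 0.0571) and 0.018 (exact p = 0.0286). These values do not show how its p behaves without a shift, so the index is read by its size more than by its p.

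Alternatives were RLE scaling, a DESeq2 1.42.0 Wald test, no filter on low counts, the replicate number as a block, each library left out in turn, all 28 libraries in 1 fit, limma with a trend on log2 of the deposited normalized value plus 1, and a fold threshold. For the index they were another signature threshold, a signature from the same segment, WT jejunum in place of WT ileum, RLE scaling, no filter and a prior count of 0.5. A count test on reads recovered from the deposited signal was added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.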

Results

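Messenger RNA was measured in 28 libraries of intestinal epithelium from mice, 7 from each of 4 segments of the gut. Satb2 encodes a chromatin-binding transcription factor, and the KO libraries came from mice with inducible, villin-driven Cre and floxed Satb2, 30 days after tamoxifen. The WT libraries carried the floxed gene without Cre. Each segment had 3 WT and 4 KO libraries, which are the n behind every mean below. Counts over all genes were 5101670, 5806535 and 6515361 in the WT jejunum libraries 1 to 3 and 3231917, 3407324 and 5379285 in WT ileum. They were 6384986, 6180089 and 6046800 in WT cecum and 5490660, 5472367 and 6630977 in WT colon. The KO jejunum libraries 1 to 4 held 6380134, 5463426, 6545452 and 4952159 counts, and the KO ileum libraries 2847807, 3125313, 5098675 and 4157983. KO cecum had 2313453, 5039021, 4485650 and 5584898 counts and KO colon 3613777, 4417129, 4794836 and 7045325. The 10 most abundant genes took between 5.44% and 12.9% of the counts of a library. Means are given in CPM (counts scaled to a common library total) with the SD between libraries, and values written with ± and no unit are log2 fold changes with their standard error. Adjusted p-values are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. Bounds and counting intervals for genes with few or no counts cover counting error only. Beside the members of a list past the test, a second count gives those adjusted over the list alone, and where it is not printed the counts were the same.

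Principal components were computed over the 12159 genes tested in all libraries. Component 1 held 44.9% of the variance, component 2 16% and component 3 8.83%. On component 1 the WT cecum and WT colon libraries lay between 83.4 and 98.5, the KO cecum and KO colon libraries between 19.6 and 52.5, and all small-intestine libraries below 0.

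**Figure D1:**
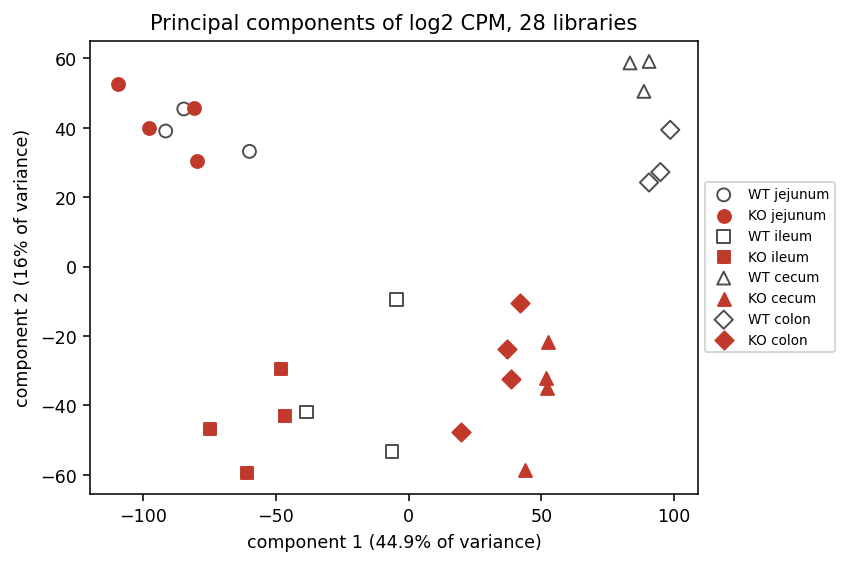
Principal components 1 and 2 (44.9% and 16% of the variance) of log2 CPM in the 28 libraries. Each point is a library, open for WT and filled for KO, with a marker for each segment.

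Satb2 lies on the minus strand of chromosome 1 at 56793981 to 56978650 (GRCm38). Its counts cover the whole gene, including exons that the Cre recombinase does not remove, and reads of antisense transcripts. In WT libraries on a scale shared by all 28, Satb2 was at 92.8, 123 and 179 CPM in colon (132 ± 43.7) and at 239, 124 and 191 CPM in cecum (185 ± 57.6). WT ileum had 15.4, 12.1 and 19.7 CPM (15.7 ± 3.84) and WT jejunum 10.48, 11.8 and 6.48 CPM (9.59 ± 2.77). The KO colon libraries had 47.9, 51.9, 66.5 and 78.8 CPM (61.3 ± 14.1) and the KO cecum libraries lay between 56.8 and 64.4 CPM (60.5 ± 4.23). KO ileum had 9.98 ± 3.25 CPM and KO jejunum 8.88 ± 1.85 CPM. Satb2 fell in KO colon (log2 fold change -1.11 ± 0.241, adjusted p = 0.00849) and in KO cecum (-1.58 ± 0.216, adjusted p = 0.000212). It did not pass the test in ileum (-0.64 ± 0.366, adjusted p = 0.406) or in jejunum (-0.12 ± 0.346, adjusted p = 0.966), where its sign turned without WT jejunum library 2. The knockout effect on Satb2 in colon did not differ past the test from that in cecum (adjusted p = 0.584), ileum (0.596) or jejunum (0.171).

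**Figure D2:**
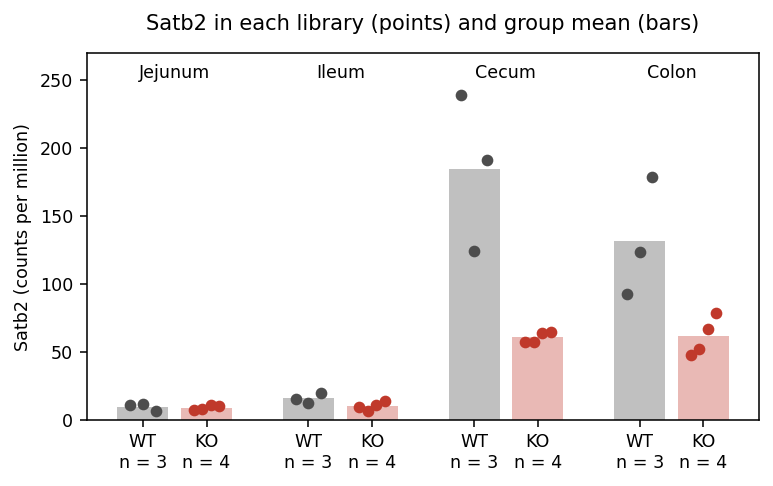
Satb2 in CPM in each of the 28 libraries, by segment and genotype, with the group mean. KO colon (61.3) and KO cecum (60.5) lay below WT colon (132) and WT cecum (185).

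The first question was which genes depend on Satb2 in the colon. In KO colon, genes of nutrient absorption that were near 0 in WT colon were abundant, and genes of salt, acid and water transport were lower. The lectin gene Lgals2 rose from 6.88 ± 3.9 to 2264 ± 375 CPM (log2 fold change 8.37 ± 0.429, adjusted p = 3.73e-07) and the retinol carrier gene Rbp2 from 5.7 to 1520 ± 815 CPM (8.07 ± 0.51). The carbonic anhydrase gene Car1 fell from 10558 ± 2483 to 4.89 ± 4.13 CPM (-11.14 ± 0.622, adjusted p = 7.76e-07). Sulfotransferase Sult1a1 fell from 482 ± 84.6 CPM by a log2 fold change of -10.52 ± 0.483. Of 11362 genes tested, 757 were higher and 986 lower in KO, and 3168 had an unadjusted p under 0.05.

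Several genes in KO colon had few or no counts in one group. The complement-related genes Cfhr2 (219 ± 103 CPM in KO) and Cfi (20.1 ± 4.12 CPM) had no count in WT colon and were at least 1384-fold and at least 118-fold higher. The crypt gene Olfm4 reached 164 ± 55.1 CPM and was higher by 1068-fold (95% counting interval 365 to 5181, on 3 counts). Myrf, a membrane-bound transcription factor, rose by a log2 fold change of 7.83 ± 0.338. In the other direction, the water channel gene Aqp8 (76.9 ± 42.6 CPM in WT) and the monocarboxylate transporter gene Slc16a9 (44.8 ± 28 CPM) had no count in KO colon and were at least 479-fold and at least 316-fold lower. The lipid transporter gene Abca12 fell by 1894-fold (95% counting interval 339 to 74848, on 1 count), and the adenylate kinase gene Ak4 by a log2 fold change of -7.51 ± 0.477.

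Genes that take up and package fat moved as a group in colon. Of 20 lipid absorption genes tested, 17 were higher and 3 did not pass, and 20 were higher when adjusted over the list alone (list adjusted p = 0.0236, camera with an estimated correlation). Mttp, which loads lipid onto lipoproteins, rose from 11.3 to 752 ± 87.8 CPM, and the fatty acid binding gene Fabp1 (7.01 ± 0.486) and acyltransferase gene Mogat2 (5.08 ± 0.302) rose too. Among 8 bile acid genes, 6 were higher and 1 was lower, as when adjusted over the list alone (list adjusted p = 0.0228). The ileal bile acid binding gene Fabp6 rose from 37.8 to 3125 ± 1441 CPM, the exporter gene Abcc2 by 7.41 ± 0.39 and the uptake transporter gene Slc10a2 by 2.93 ± 0.335. Brush-border digestive enzymes were higher for 16 of 17 genes, also over the list alone (list adjusted p = 0.033), with sucrase-isomaltase Sis going from 20 ± 11.6 to 2976 ± 580 CPM (7.22 ± 0.448). Peptidase Enpep rose by 5.99 ± 0.445 and trehalase Treh by 5.27 ± 0.378.

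Transporters of sugars, amino acids and peptides were higher for 11 and lower for 1 of 13 genes, with the same numbers when adjusted over the list alone (list adjusted p = 0.0448). Examples were the amino acid carriers Slc6a19 (189 ± 117 CPM in KO, 1.94 in WT) and Slc43a2 (3.38 ± 0.277). Vitamin and mineral uptake genes were higher for 8 of 12 and over the list alone for 9 (list adjusted p = 0.0236), among them the anion exchanger gene Slc26a6 (7.21 ± 0.288) and the calcium-binding gene S100g (2.85 ± 0.299). Colonocyte ion and water transport genes went down: 12 of 21 were lower and 0 higher, and 12 lower and 1 higher when adjusted over the list alone (list adjusted p = 0.033). Aqp4 fell from 281 to 36.3 CPM, and the sodium channel subunit gene Scnn1b (10.6 CPM in WT) fell by 210-fold (95% counting interval 37.3 to 8340, on 1 count). Other colon-enriched markers were split, with 2 higher and 7 lower of 19 (list adjusted p = 0.654). The count of 6 lists past the test was 1 without WT colon library 1, 0 without WT colon library 2 or 3, 1 without KO colon library 3 and 3 without KO colon library 4.

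Secretory cell genes in KO colon changed in mixed directions. Paneth cells are granule-bearing cells of small-intestine crypts, and 9 of 12 of their markers were higher and 1 lower (10 and 1 when adjusted over the list alone, list adjusted p = 0.353). Lyz1, for lysozyme, rose from 2.33 to 244 ± 140 CPM (6.74 ± 0.643) and the defensin-processing protease gene Mmp7 by 3.25 ± 0.405, and Nupr1 fell by 3.52 ± 0.348. Goblet cell markers went both ways, with 5 higher and 8 lower of 19 (5 and 9 over the list alone, list adjusted p = 0.451). The mucin gene Muc2 fell from 6701 ± 578 to 1540 ± 319 CPM (-2.12 ± 0.229, adjusted p = 7.88e-05) with the glycosylation gene Galnt12 (-1.36 ± 0.164), whereas Reg4 rose from 24.2 to 1749 ± 1360 CPM and Tff3 by 2.62 ± 0.279. Enteroendocrine markers were higher for 7 and lower for 2 of 17 (list adjusted p = 0.107), with the hormone genes Ghrl (26.8 against 0.427 CPM) and Cck (3.84 ± 0.34) up and the granin gene Chga (-2.17 ± 0.282) down. Tuft cells sense luminal chemicals, and 9 of their 11 markers were higher, also over the list alone (list adjusted p = 0.441), including Trpm5 (2.65 ± 0.45) and Avil (2.49 ± 0.464).

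Regulators and metabolic genes changed in both directions in KO colon. Of 27 transcription factor genes, 8 were higher and 6 lower (9 and 6 over the list alone), with Creb3l3 (6.77 ± 0.519), Maf (3.91 ± 0.304) and Gata5 (3.17 ± 0.371) higher and Pparg (-1.92 ± 0.156) lower. Among 7 posterior Hox genes 1 was lower, Hoxd8 (-3.85 ± 0.47, adjusted p = 0.00019). Stem cell markers were higher for 4 and lower for 2 of 16 (4 and 3 over the list alone) and 1 of 20 cell cycle genes was higher. Cholesterol synthesis genes were higher for 7 of 19 (9 over the list alone, list adjusted p = 0.451), fatty acid oxidation genes for 2 of 16 with 1 lower (3 and 1 over the list alone), and xenobiotic metabolism genes for 10 of 23 with 5 lower (12 and 5 over the list alone, list adjusted p = 0.617).

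Interferon and T cell genes in KO colon were lower where they changed. Of 21 genes of antigen presentation and the interferon-gamma response, 15 were lower and 0 higher, and 21 were lower when adjusted over the list alone (list adjusted p = 0.316). The guanylate-binding gene Gbp2 fell from 102 to 18.9 CPM (-2.41 ± 0.276) and the GTPase gene Iigp1 from 395 to 38.1 CPM (-3.36 ± 0.523). Type I interferon response genes were lower for 4 of 17 (10 over the list alone, list adjusted p = 0.272), as in Ifit2 (-2.76 ± 0.263). T cell markers were lower for 4 of 13 (9 over the list alone, list adjusted p = 0.451), with the chemokine gene Ccl5 falling from 42.8 to 10 CPM. Antimicrobial genes were higher for 3 and lower for 4 of 14 (3 and 5 over the list alone). Lower genes numbered 1 of 5 myeloid markers and 1 of 7 fibroblast markers (2 over the list alone). No gene passed among 17 dissociation stress genes, 15 unfolded protein genes, 1 endothelial marker and 2 pancreatic genes by edgeR. B cell and squamous markers had no member with enough counts to test, and mitochondrial genes were absent from the count table. 6 of the 27 lists passed with an estimated correlation and 14 with a preset one.

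**Figure D3:**
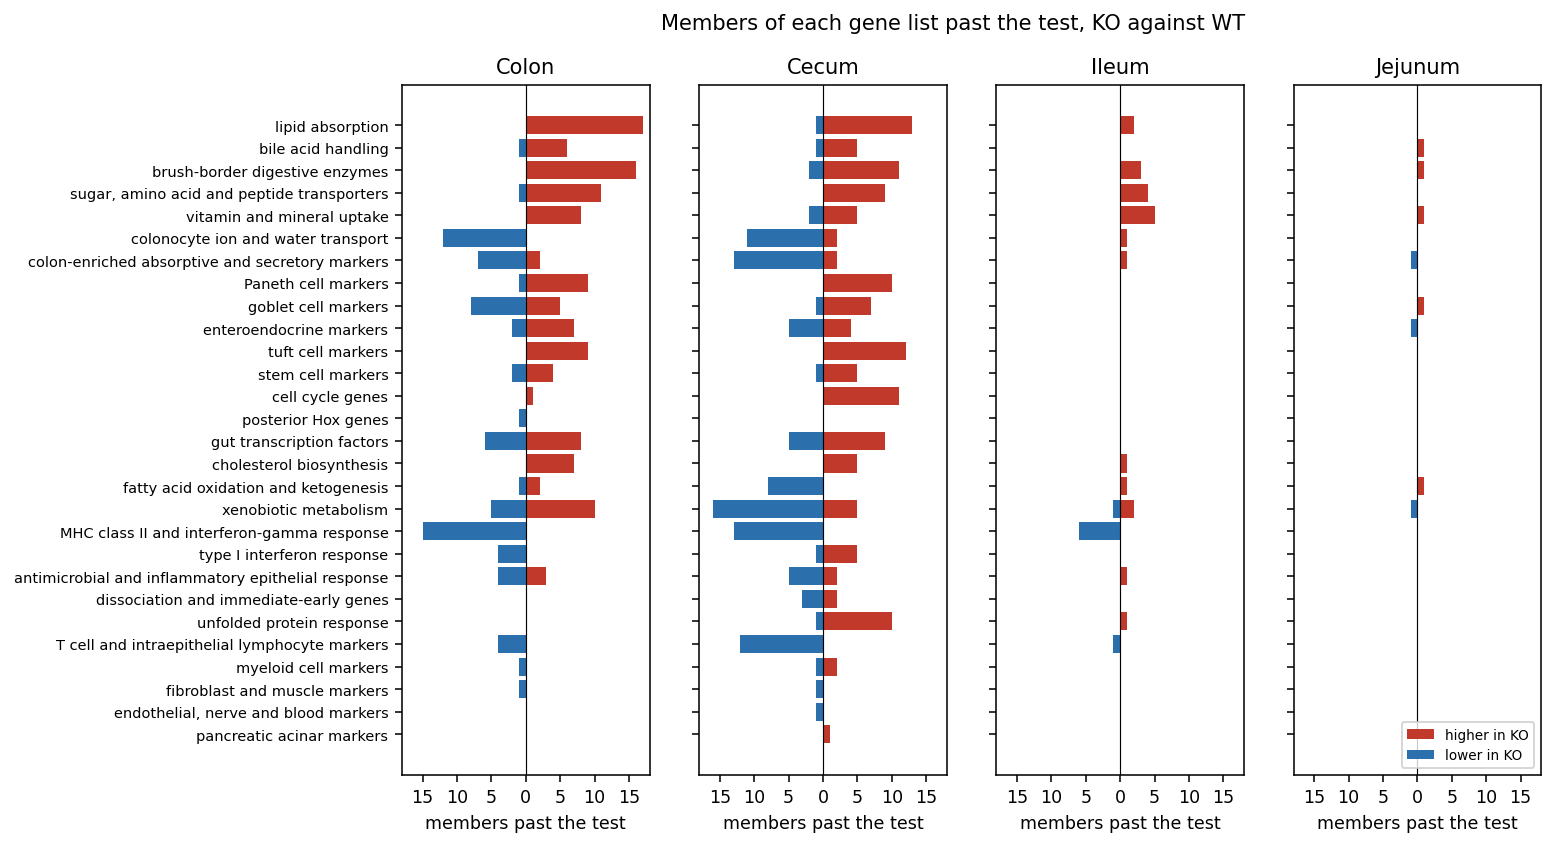
Number of members of each fixed gene list that were higher (right of 0) or lower (left of 0) in KO than in WT, for each segment. Lipid absorption genes were higher for 17 of 20 in colon and for 13 of 19 in cecum.

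The same question was asked in the cecum, the other segment with high Satb2. The lists of lipid absorption, bile acid, brush-border and nutrient transport genes passed upward in KO cecum, and that of ion and water transport genes passed downward. Lgals2 rose from 2.1 to 2332 ± 305 CPM (10.11 ± 0.355, adjusted p = 7.31e-09), and the sugar phosphate exchanger gene Slc37a2 fell from 2950 ± 910 to 0.438 CPM (-13.24 ± 0.572). The phospholipase gene Pla2g4c rose to 2216 ± 1703 CPM (10.44 ± 1.16, adjusted p = 4.04e-05). Of 11126 genes tested, 1528 were higher and 1752 lower in KO, and 4504 had an unadjusted p under 0.05. The number higher was 866 without WT cecum library 1, 971 without WT cecum library 3 and 981 with a threshold of 2-fold.

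As in colon, some genes were all but switched on or off in KO cecum. Cfhr2 (220 ± 69.2 CPM), Cfi and the small-RNA pathway gene Piwil2 had no count in WT cecum and were at least 1394-fold, at least 154-fold and at least 171-fold higher, and Olfm4 was higher by 814-fold (95% counting interval 225 to 6726, on 2 counts). In the other direction, Aqp8 (1226 ± 208 CPM in WT) fell by 22398-fold (95% counting interval 4020 to 884699, on 1 count), the raft protein gene Mal (1952 ± 464 CPM) by 17868-fold (95% counting interval 4946 to 147548, on 2 counts) and Sult1a1 (914 ± 241 CPM) by 5548-fold (95% counting interval 1898 to 26906, on 3 counts). St3gal5, Slc16a9 and the calcium channel gene Trpv6 had no count in KO cecum and were at least 817-fold, at least 524-fold and at least 179-fold lower.

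Lipid absorption genes were higher for 13 and lower for 1 of 19 in cecum (14 and 1 over the list alone, list adjusted p = 0.00527), with Mttp going from 5.45 to 411 CPM and the cholesterol uptake gene Npc1l1 rising by 6.80 ± 0.349. Bile acid genes were higher for 5 and lower for 1 of 8 (6 and 1 over the list alone, list adjusted p = 0.0298). Fabp6 rose from 3.71 to 922 ± 258 CPM and Abcc2 by 6.25 ± 0.537, and Abcc3 fell by 1.99 ± 0.277. Brush-border enzymes were higher for 11 and lower for 2 of 17 (14 and 2 over the list alone, list adjusted p = 0.00833): Sis rose from 4.92 to 1086 ± 290 CPM, the carboxypeptidase gene Ace2 by 5.83 ± 0.383, and the metalloprotease gene Mep1a fell from 505 to 66.7 CPM. Nutrient transporters were higher for 9 and lower for 0 of 12, also over the list alone (list adjusted p = 0.00833), with Slc7a9 (6.80 ± 0.359) and Slc6a19 (5.23 ± 0.374) among them. Vitamin and mineral genes were higher for 5 and lower for 2 of 13 (5 and 3 over the list alone, list adjusted p = 0.167).

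Ion and water transport genes were lower for 11 and higher for 2 of 20 in cecum (13 and 3 over the list alone, list adjusted p = 0.00833). Car2 fell from 1705 ± 105 to 7.37 CPM (-7.87 ± 0.335), the chloride exchanger gene Slc26a3 from 2102 ± 399 to 88.8 CPM and the short-chain fatty acid carrier gene Slc5a8 by 3.78 ± 0.291. Colon-enriched markers were lower for 13 and higher for 2 of 18 (14 and 2 over the list alone, list adjusted p = 0.117), including Emp1 (-3.96 ± 0.334), Prdx6 (-3.59 ± 0.217) and the ketone body gene Hmgcs2 (-3.28 ± 0.419). Xenobiotic metabolism genes were lower for 16 and higher for 5 of 22, also over the list alone (list adjusted p = 0.194). Cyp2c55 fell from 7148 ± 469 to 31.3 CPM and Ugt1a1 by 3.38 ± 0.243, with reads that near-identical family members may share. Fatty acid oxidation genes were lower for 8 of 16 (8 lower and 1 higher over the list alone, list adjusted p = 0.327).

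Tuft, Paneth and cell cycle markers past the test were higher in KO cecum, and none of these lists passed camera. All 12 tuft markers were higher, also over the list alone (list adjusted p = 0.194), as in Alox5ap (3.92 ± 0.582) and Avil (3.77 ± 0.501). Paneth markers were higher for 10 of 12, also over the list alone (list adjusted p = 0.221), with Lyz1 at 625 ± 468 CPM against 1.44 and Ang4 higher by 6.36 ± 0.668. Goblet markers were higher for 7 and lower for 1 of 19 (11 and 1 over the list alone, list adjusted p = 0.582), and Muc2 rose from 388 ± 106 to 1280 ± 718 CPM with its regulator Spdef (1.66 ± 0.294). Stem cell markers were higher for 5 and lower for 1 of 14 (list adjusted p = 0.212), among them Smoc2 (1.90 ± 0.252) and the Wnt target gene Axin2 (1.83 ± 0.318). Cell cycle genes were higher for 11 of 20 (13 over the list alone, list adjusted p = 0.212), such as Birc5 (0.98 ± 0.194), and enteroendocrine markers were higher for 4 and lower for 5 of 12. Transcription factor genes were higher for 9 and lower for 5 of 28 (9 and 7 over the list alone), with Creb3l3 up (4.39 ± 0.33) and Pparg down (-2.45 ± 0.203).

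Unfolded protein response genes were higher for 10 and lower for 1 of 15 in cecum (13 and 1 over the list alone, list adjusted p = 0.297), with the chaperone gene Hspa5 (1.13 ± 0.221) and Creld2 (1.44 ± 0.248) up and Dnajb9 (-1.46 ± 0.276) down. Antigen presentation genes were lower for 13 of 20 (14 over the list alone, list adjusted p = 0.212), as in H2-Aa, which fell from 896 to 40.8 CPM, and its activator Ciita (-3.82 ± 0.406). Type I interferon genes were higher for 5 and lower for 1 of 16 (7 and 1 over the list alone, list adjusted p = 0.713), among them Rsad2 (2.44 ± 0.582, adjusted p = 0.00807). T cell markers were lower for 12 of 13 (13 over the list alone, list adjusted p = 0.327), including Cd3e (-3.77 ± 0.657) and Cd7 (-3.83 ± 0.66). The macrophage gene C1qa fell by 5.68 ± 0.656, and the endothelial gene Pecam1 by 60.4-fold (95% counting interval 16.3 to 504, on 2 counts). 5 of the 27 lists passed with an estimated correlation and 18 with a preset one.

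Colon and cecum calls were then set side by side to ask whether the loss of Satb2 touched the same genes. The comparisons share no library, but the labels do not say whether the same animals gave both segments. Of 10927 genes tested in both, 453 were higher in both, where 709 and 1488 calls would share 96.55 if independent, and 545 were lower in both, where 861 and 1675 calls would share 132. Opposite directions were called for 61 genes, against 225.9. In a test of the difference itself, the knockout effect differed between colon and cecum for 637 of 12159 genes, with 443 more positive and 194 more negative in colon. This number was 401 without WT cecum library 1 and 420 without WT colon library 2. The chloride channel regulator gene Clca6 changed by 2.39 (log2) in colon and -3.97 in cecum (difference 6.36 ± 0.564, adjusted p = 3.05e-08), and the magnesium channel gene Trpm6 by -0.11 and -7.01 (6.90 ± 0.742). St3gal4 changed by 2.12 and 9.18 (difference -7.06 ± 0.434) and the interferon-induced gene Ifi44 by -2.57 and 3.79 (-6.36 ± 1.41).

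**Figure D4:**
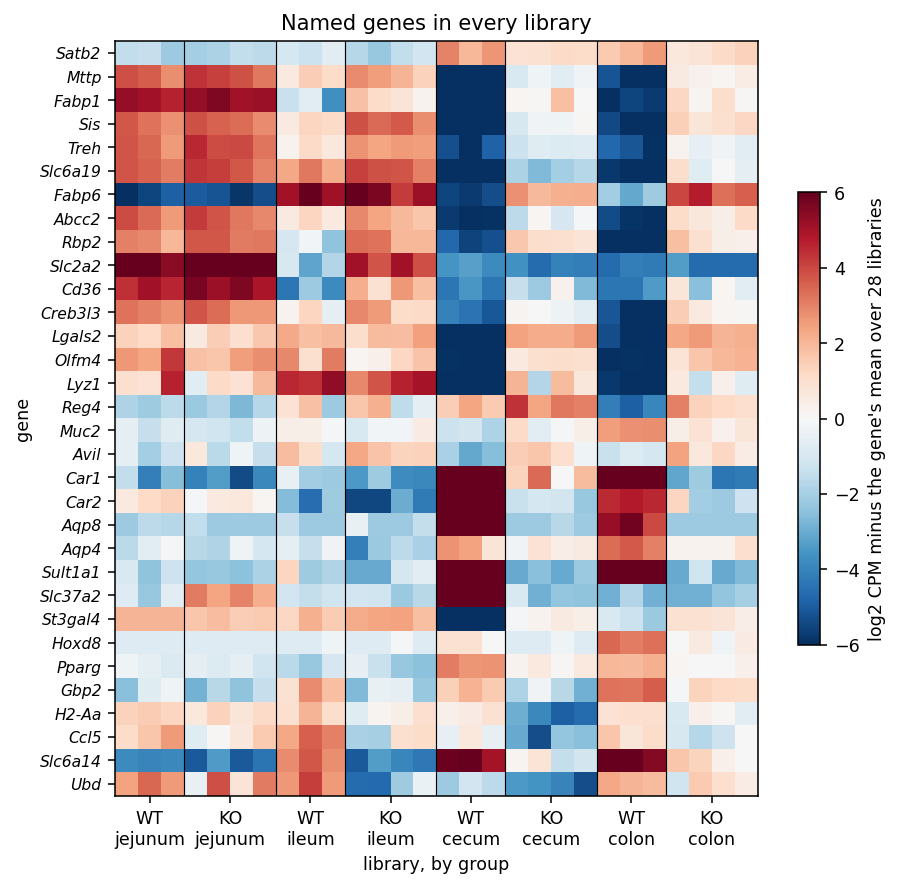
Log2 CPM of genes named in the text in each of the 28 libraries, relative to the mean of each gene, with genes in rows and libraries by group in columns. Absorptive genes such as Mttp were higher in KO than in WT colon and cecum libraries.

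In the ileum, where WT Satb2 was at 15.7 CPM, the question was whether genes change with Satb2 low to begin with. Genes for the uptake of sugar and folate were among those higher in KO ileum: the glucose transporter gene Slc2a2 rose from 2.28 to 196 ± 90.5 CPM (6.39 ± 0.579, adjusted p = 0.000208) and the folate transporter gene Slc46a1 by 3.97 ± 0.541. The alcohol dehydrogenase gene Adh6a rose from 10.3 to 279 CPM, the esterase gene Bche from 28 to 391 CPM and the fatty acid receptor gene Cd36 by 6.04 ± 0.731. Cyp2c29 was higher by 836-fold (95% counting interval 150 to 33040, on 1 count). The peptidase gene Mme rose by 2.55 ± 0.345. The amino acid transporter gene Slc6a14 fell from 103 ± 37 to 0.35 CPM (-8.08 ± 0.47, adjusted p = 6.25e-06), the interferon-induced gene Ubd from 184 to 4.57 CPM, and Ceacam10 (-3.41 ± 0.538) and the muscle actin gene Acta1 (-3.61 ± 0.564) fell as well.

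Other ileum calls ended when a WT library was left out, while their log2 fold changes kept their direction and most of their size. Sis rose from 2101 ± 551 to 11207 ± 3105 CPM (2.42 ± 0.422, adjusted p = 0.0163), but had an adjusted p of 0.129 without WT ileum library 1 (2.21) and 0.0638 without library 3 (2.50), in a range of 7.16e-12 to 0.129 over its alternatives. Without WT ileum library 1 the adjusted p was 0.0841 for Rbp2 (3.72 ± 0.593), 0.0581 for the fructose transporter gene Slc2a5 (1.87 ± 0.282) and 0.0563 for Treh (1.78 ± 0.274), each the highest over alternatives that went down to 1.54e-11, 3.12e-08 and 3.02e-08. Their log2 fold changes in that fit were 3.68, 1.81 and 1.58. Gbp2 fell by 3.35 ± 0.582 and had an adjusted p of 0.0729 without WT ileum library 2 (-2.77), in a range of 3.71e-06 to 0.0729.

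Of 10331 genes tested in ileum, 106 were higher and 40 lower, and 1702 had an unadjusted p under 0.05. The number higher was 21, 69 and 49 without WT ileum library 1, 2 or 3, and 70, 57 and 162 without KO ileum library 1, 2 or 3. The number lower was 13, 10 and 22 without those WT libraries and 26, 13 and 68 without those KO libraries. These counts also depended on the method: 415 were higher and 156 lower by DESeq2, 318 and 152 without a filter on low counts, and 489 and 349 with all 28 libraries in 1 fit, and 23 were lower by limma. Nutrient transporters were higher for 4 of 16 (8 over the list alone, list adjusted p = 0.207), vitamin genes for 5 of 12 (6 over the list alone, list adjusted p = 0.207), brush-border enzymes for 3 of 18 (6 over the list alone) and lipid absorption genes for 2 of 19 (11 over the list alone). Cholesterol synthesis genes were higher for 1 of 19 and, over the list alone, for 17 (list adjusted p = 0.284). Antigen presentation genes were lower for 6 of 20 (20 over the list alone, list adjusted p = 0.207) and T cell markers for 1 of 13 (13 over the list alone, list adjusted p = 0.207). No list passed camera with an estimated correlation in ileum, where 15 passed with a preset one.

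Jejunum, with the lowest Satb2 in WT, gave few calls for the same question. The stress-hormone response gene Fkbp5 rose from 5.19 to 203 ± 93 CPM (5.28 ± 0.435, adjusted p = 0.000218) and Slc16a9, which was lost in KO colon, rose from 0.234 to 48.3 ± 35.9 CPM (7.38 ± 0.748). Slc37a2 (4.09 ± 0.515) and Pcp4l1 (3.47 ± 0.358) also rose, and the kinase gene Pkdcc fell (-3.16 ± 0.391). The enteropeptidase gene Tmprss15 rose by 5.59 ± 0.817 and the carboxylesterase gene Ces1d by 2.70 ± 0.378, with adjusted p-values of 0.0583 and 0.0645 without WT jejunum library 2, the highest over alternatives that went down to 9.34e-10 and 3.79e-09, at log2 fold changes of 5.93 and 2.64 in that fit. The metabolic switch gene Pdk4 rose by 4.27 ± 0.775 (adjusted p = 0.0399), with an adjusted p of 0.087 and 0.107 without WT jejunum library 1 or 3 and 0.0875 and 0.125 without KO jejunum library 2 or 3, in a range of 5.96e-07 to 0.125, while the log2 fold change in these 4 fits was 3.77 to 4.49. The metallothionein gene Mt2 fell from 18.8 to 2.19 CPM, with an adjusted p of 0.057, 0.06, 0.0936 and 0.0614 without the same libraries, in a range of 6.05e-07 to 0.0936, and log2 fold changes of -3.22 to -2.71 there.

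Of 10410 genes tested in jejunum, 23 were higher and 7 lower, and 803 had an unadjusted p under 0.05. The number higher was 14, 8 and 15 without WT jejunum library 1, 2 or 3 and 9, 15 and 45 without KO jejunum library 2, 3 or 4. The number lower was 4 without WT jejunum library 2, and it was 3, 2 and 12 without those KO libraries. DESeq2 called 93 higher and 33 lower, no filter on low counts gave 88 and 32, and 1 fit of all 28 libraries gave 42 and 11. No list had more than 1 member past the test, and type I interferon genes had 6 of 16 higher when adjusted over the list alone (list adjusted p = 0.705). No list passed camera with an estimated correlation, and 9 passed with a preset one.

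The knockout effect in colon was tested against the effects in the small intestine. It differed from that in ileum for 480 of 12159 genes (262 more positive and 218 more negative in colon) and from that in jejunum for 589 (360 and 229). The urea cycle gene Cps1 changed by 7.70 (log2) in colon and -1.28 in ileum (difference 8.98 ± 0.766, adjusted p = 4.75e-09). Car1 differed by -9.12 ± 1.10 and Sult1a1 by -8.90 ± 1.42 between colon and ileum. Lgals2 changed by 8.38 in colon and -0.28 in jejunum (8.66 ± 0.516), and Lyz1 (8.90 ± 1.33), Car1 (-9.28 ± 1.16) and the semaphorin receptor gene Nrp2 (-7.66 ± 1.11) also differed between colon and jejunum.

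Wild-type segments were compared to give the regional differences that the knockout effects can be set against. Defensin, absorptive and patterning genes were among those that differed between WT ileum and WT colon. The defensin genes Defa21 (3954 against 0.902 CPM, 12.12 ± 0.63) and Defa22 (log2 fold change 12.40, adjusted p = 2.24e-07) were higher in ileum and Defa26 was at least 809-fold higher, although these near-identical copies may share reads. Slc6a19 (1031 against 1.74 CPM), the sterol exporter gene Abcg8 (8.91 ± 0.528) and Fabp6 (7980 ± 3188 against 33.9 CPM) were higher as well. Lower in ileum were Satb2 (-3.04 ± 0.31, adjusted p = 2.52e-05), Car1 (17.5 against 9485 CPM), Car2 (-7.40 ± 0.477) and Aqp4 (-3.97 ± 0.344). The forkhead gene Foxd2 and Slc16a9 had no count in WT ileum and were at least 237-fold and at least 153-fold lower, Hoxa10 was lower by 108-fold (95% counting interval 19.1 to 4270, on 1 count) and Hoxb9 by 0.91 ± 0.212. Higher in ileum were 12 of 14 Paneth markers, 17 of 17 brush-border genes, 17 of 19 lipid genes and 14 of 15 nutrient transporters (list adjusted p = 0.0855 for each), and 6 of 8 bile acid genes (7 over the list alone, list adjusted p = 0.149). Ion and water transport genes were lower for 12 of 20, the 1 list past camera (list adjusted p = 0.0454), and Hox genes for 4 of 4 (0.0855). In all, 1399 genes were higher and 1155 lower of 11324. The number higher was 884 without WT ileum library 2, 861 and 740 without WT colon library 2 or 3, and the number lower was 707 without WT colon library 3.

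Genes of lipid, sugar and bile acid handling were among those that differed between WT jejunum and WT ileum. The lactase gene Lct (2954 ± 1457 against 1.83 CPM, 10.69 ± 0.637), Cd36 (8.70 ± 0.579), Slc2a2 (8.02 ± 0.594), Apoa4 (12523 against 488 CPM), Gata4 (6.62 ± 0.367) and Cyp3a11 (4.93 ± 0.517) were higher in jejunum. Fabp6 (3.07 against 6638 CPM), Slc10a2 (-8.09 ± 0.482) and the tuft marker Dclk1 (-2.66 ± 0.531) were lower, and Fgf15 and Hoxb8, with no count in WT jejunum, were at least 348-fold and at least 60-fold lower. Satb2 did not pass (-0.80 ± 0.364, adjusted p = 0.153). Lipid genes were higher in jejunum for 15 of 19 (18 over the list alone), sugar, amino acid and peptide transporters for 10 of 16 with 1 lower (12 and 1 over the list alone) and xenobiotic genes for 16 of 24 (17). Bile acid genes were lower for 6 of 8, Paneth markers for 10 of 14 (12 over the list alone), goblet markers for 13 of 19 (15) and tuft markers for 8 of 9, while no list passed camera (15 did with a preset correlation). Of 10693 genes, 915 were higher and 995 lower. Without WT jejunum library 1, WT jejunum library 2 or WT ileum library 1 these were 497 and 456, 430 and 313, and 472 and 303, and 616 genes were lower without WT ileum library 2. With all 28 libraries in 1 fit, 1492 were higher.

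WT cecum and WT colon did not differ past the test in Satb2 (0.46 ± 0.274, adjusted p = 0.323). Slc37a2 was higher in cecum by 18436-fold (95% counting interval 6308 to 89400, on 3 counts) and the homeobox gene Pitx2 by 2407-fold (95% counting interval 666 to 19881, on 2 counts), and Reg4 (6.12 ± 0.383), Aqp8 (4.04 ± 0.405), Slc26a3 (3.27 ± 0.232), Hoxa9 (2.75 ± 0.407) and Hoxa10 (2.46 ± 0.372) were higher too. St3gal4 (1.75 against 350 CPM), Osr2 (-4.36 ± 0.217), Hoxd8 (-3.17 ± 0.481), Gbp2 (-1.69 ± 0.225) and Muc2 (390 against 6562 CPM) were lower. Antigen presentation genes were lower in cecum for 16 of 21 (19 over the list alone) and goblet markers for 12 of 19, xenobiotic genes were higher for 14 of 21 (15), and no list passed camera (13 did with a preset correlation). Of 11301 genes, 747 were higher and 836 lower, with 395 and 505 without WT cecum library 1 and 400 and 547 without WT colon library 2. A threshold of 2-fold left 430 higher, and with all 28 libraries in 1 fit 546 were lower.

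How far KO colon and KO cecum moved toward ileum was measured with the small-intestine index, which is 0 at WT of the segment and 1 at WT ileum. KO colon libraries lay at 0.541 ± 0.0638 (range 0.474 to 0.628) over 1048 genes and KO cecum libraries at 0.453 ± 0.0468 (range 0.415 to 0.512) over 896 genes. The SD between WT libraries was 0.041 and 0.0187, and the exact permutation test over 35 splits gave p = 0.0286 in each, two-sided, the smallest p possible. The part of the index from genes lower in ileum was 0.622 in colon and 0.647 in cecum, and the part from genes higher in ileum was 0.501 and 0.360. Of signature genes higher in ileum, 316 of 583 tested rose and 27 fell in KO colon, and 247 of 428 rose and 53 fell in KO cecum. Of those lower in ileum, 222 of 368 fell and 3 rose in KO colon, and 203 of 344 fell and 18 rose in KO cecum. With WT jejunum in place of WT ileum the index was 0.384 in colon and 0.238 in cecum.

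**Figure D5:**
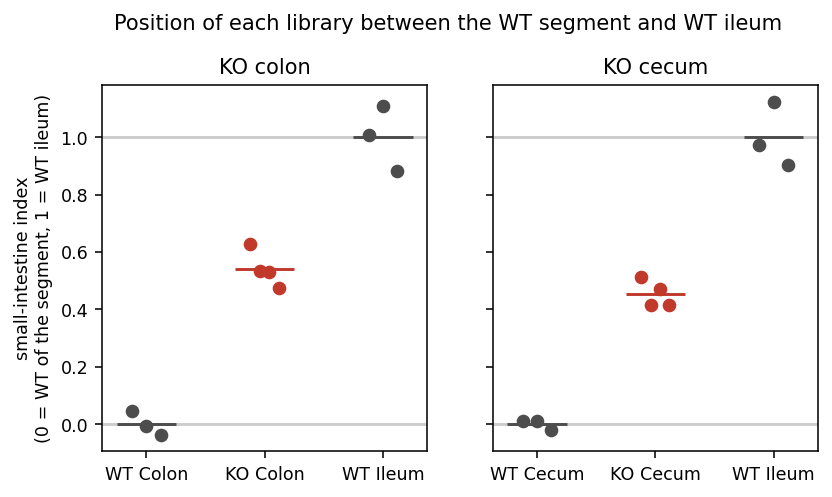
Small-intestine index of each library in WT, KO and WT ileum groups, for colon and cecum, with the group mean (0 is the mean of WT of the segment and 1 the mean of WT ileum). KO colon libraries lay between 0.474 and 0.628 and KO cecum libraries between 0.415 and 0.512.

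What still set KO colon apart from WT ileum was tested directly. Patterning genes of the posterior gut were among those higher in KO colon: Foxd2 (39.6 CPM) and Hoxa9 had no count in WT ileum and were at least 145-fold and at least 63.4-fold higher in KO colon, and Hoxa10 was higher by 312-fold (95% counting interval 55.7 to 12323, on 1 count). Satb2 (1.97 ± 0.262, adjusted p = 0.00137) and Cck (2.38 ± 0.435) were higher too. Lyz1 (220 against 6762 CPM), Defa21 (34.3 against 3861 CPM), the peptidase gene Anpep (-2.38 ± 0.359), the vitamin B12 receptor gene Amn (-2.40 ± 0.311), Slc25a48 (-7.11 ± 0.476) and the T cell genes Ccl5 (-3.96 ± 0.431) and Cd3g (-3.68 ± 0.525) were lower. The homeobox gene Pitx1 had no count in KO colon and was at least 290-fold lower. Hox genes were higher for 4 of 4 (list adjusted p = 0.0667). Paneth markers were lower for 11 of 14 (13 over the list alone), brush-border genes for 13 of 17 (16), nutrient transporters for 12 of 15 (14) and T cell markers for 12 of 13, and lipid genes were higher for 3 and lower for 8 of 20 (4 and 12). No list passed camera with an estimated correlation and 13 passed with a preset one. Of 10996 genes, 308 were higher and 559 lower in KO colon. These were 140 and 319 without WT ileum library 2, 557 and 850 without WT ileum library 3, 186 and 351 without KO colon library 2, and 200 and 370 without KO colon library 3, and 178 genes were higher without KO colon library 4. DESeq2 called 502 higher, and 1 fit of all 28 libraries called 464 higher and 936 lower.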

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

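The tests of small-intestine cells mixed into KO colon by their abundant transcripts, of KO ileum pieces taken nearer to the jejunum, and of effect sizes without or against 1 WT ileum library, were chosen only after the results were seen.

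Among the named genes, 14 of 160 groups of 4 KO libraries had 1 library far from the other 3, where chance alone sets about 1 in 20 groups apart, or 8 of 160. In KO colon these were library 1 for Reg4 (3780 CPM, the others 917 to 1241) and Nr1d1 (49.6 CPM, the others 33.2 to 35), library 2 for Sult1a1 (1.19 CPM, the others 0 to 0.133), library 3 for Abca12 (0.206 CPM, the others 0) and library 4 for Aqp4 (52.9 CPM, the others 30.7 to 30.8) and Scnn1b (0.133 CPM, the others 0). Library 1 also stood apart for Anpep on the scale of the comparison with WT ileum (2759 CPM, the others 1637 to 1710). In KO cecum, library 1 stood apart for Slc37a2 (1.38 CPM, the others 0 to 0.206), library 3 for Aqp8 (0.206 CPM, the others 0) and library 4 for Cd7 (2.66 CPM, the others 0.46 to 0.823). Library 4 of KO ileum had the least Bche (242 CPM, the others 436 to 443) and library 1 the most Cyp2c29 (209 CPM, the others 29.4 to 35.6). Library 1 of KO jejunum had the most Slc16a9 (102 CPM, the others 25.4 to 33.8) and library 2 the most Tmprss15 (133 CPM, the others 17.3 to 32.1). Several of these genes had few counts, so that a single read can set a library apart.

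Effects of the knockout differed between segments for 637 genes between colon and cecum, 480 between colon and ileum and 589 between colon and jejunum, by a test of the difference itself. Between colon and cecum the log2 differences were 6.36 for Clca6, 6.90 for Trpm6, -7.06 for St3gal4 and -6.36 for Ifi44. Against ileum they were 8.98 for Cps1, -9.12 for Car1 and -8.90 for Sult1a1, and against jejunum 8.66 for Lgals2, 8.90 for Lyz1, -9.28 for Car1 and -7.66 for Nrp2. Over 34 splits each, the real one included, the highest other split gave 238 genes for ileum and 154 for jejunum. For cecum 2 of 34 splits gave as many genes as the real one, and the other gave 968. That split exchanged the labels of all 3 WT cecum libraries and left 3 of 4 KO colon labels in place. It thus turns the knockout effects themselves into a difference between segments, a structure of the samples. The splits with 238 and 154 genes likewise gave KO labels to all 3 WT colon libraries. Only some of the possible splits were drawn, and they treat the libraries of different segments as independent. These counts therefore do not exclude chance for any of the segments.

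Small-intestine genes were high in the KO colon libraries. Small-intestine epithelium mixed into these libraries would have to make up a share of 0.948 to leave 14 colon genes at a median of 0.0516 of their WT level, but 54 abundant small-intestine genes stood at a median of 0.364 of the lowest small-intestine group, with an upper quartile of 0.536, and 45 of them lay below that share. This argues only against mixing as the one source of both changes. A smaller share mixed in, beside a loss of colon genes from another source, was not tested. For the posterior Hox genes another share was used, 0.429, the median level of 664 signature genes in KO colon relative to WT ileum. Cells without Hox transcripts at that share would lower them to -0.808 (log2). WT ileum held Hoxb9 at 40.9 CPM, so that value is too low for this gene. The median change of the Hox genes was 0.515, but with an SD of 2.45 over 4 genes this value alone decides little. Depth is argued against by the 1598 genes that passed after all colon libraries were thinned to 3613777 counts. An effect of Cre or its induction without loss of Satb2 could not be told apart from the knockout, since no library had Cre without floxed Satb2. In jejunum the 1354 colon genes tested moved by a median of 0.1 (upper bootstrap bound 0.132), below the bound of 0.249 set from their median of 1.24 in colon, which argues only against a Cre effect of like size in every segment. In ileum the 1399 tested there moved by a median of 0.522, above that bound, so that an effect shared by colon and ileum stays open. The bound was first set on jejunum alone, which was too narrow because ileum libraries carry Cre as well, and ileum was added after its value was seen. Loss of Satb2 in the epithelium remains a hypothesis that may account for the pattern.

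Some genes higher in WT jejunum than in WT ileum, such as Slc2a2 and Cd36, rose in KO ileum, where 4 of 16 nutrient transporters were higher (list adjusted p = 0.207) and no list passed camera. Pieces taken nearer to the jejunum would have lowered 6 bile acid genes to a median of -2.16 (log2), and their median change was 0.309 (SD 0.799). That prediction came from genes chosen with the same WT ileum libraries as the KO comparison. With genes chosen without a WT library and KO ileum measured against that library alone, the bile acid genes lay above the prediction by more than their SD for libraries 1 (0.708, predicted -2.97) and 3 (0.327, predicted -0.671), but not for library 2 (-0.156, predicted -1.22, SD 1.41). Such a source was thus not shown and stays open. A single WT ileum library that stands apart could not be told apart from an effect of the knockout. The 69 genes past the test and higher in both KO ileum and WT jejunum kept a median log2 fold change of 1.90 or more without any 1 of the libraries, but this follows from how they were chosen and decides nothing. Against WT libraries 1, 2 and 3 left out of the choice, genes higher in WT jejunum stood at a median of 1.04, 0.4 and 0.174 in KO ileum. The number of genes past the test fell from 146 to 34, 79 and 71 without libraries 1, 2 and 3. It fell without each of them, but most without library 1, against which genes higher in WT jejunum also stood highest in KO ileum. Part of the fall follows from fewer libraries. Other values set libraries 2 and 3 apart. On component 2 WT ileum library 3 lay at -9.54 and libraries 1 and 2 at -53.2 and -41.9. On component 1 library 2 stood apart (-38.4, libraries 1 and 3 at -6.3 and -4.5). Without library 3 the calls between WT jejunum and WT ileum rose to 1173 higher and 1371 lower, from 915 and 995. Cre without loss of Satb2 and differences that were not recorded were not tested in ileum, and loss of Satb2 stays among the open explanations.

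Fkbp5, Pdk4 and Mt2, which respond to stress hormones or fasting, differed between KO and WT jejunum. A different time of day at collection may produce such a pattern, and clock genes were used to test it: evening minus morning genes differed by -0.377 ± 0.208 (log2, KO minus WT) in jejunum (exact permutation p = 0.229, two-sided, adjusted p = 0.305 over 4 segments). This neither showed a shift in time nor ruled one out: 6 of 14 clock genes passed over the list alone, in directions that cancel in the contrast, and a single segment could reach an adjusted p of 0.114 at best. Single clock genes passed the test in cecum (4 of 13) and colon (4 of 13), led by Dbp in cecum (-3.62). A different time of collection for KO and WT and a change of the clock in the knockout therefore stay open in cecum and colon, and with them chance in jejunum and ileum, where no clock gene passed. The labels give no time of collection. Feeding or handling was not recorded, and the knockout itself stays open.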

How the results depend on the processing

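Among the processing alternatives only the count test on recovered reads was chosen after the data were seen, and it gave the same counts in the 4 KO comparisons. RLE scaling moved no count by over 1.5 times. The index stayed positive, at 0.384 to 0.593 in colon and 0.238 to 0.548 in cecum over the alternatives with all libraries and at 0.483 to 0.577 and 0.414 to 0.501 without 1 library. Its exact p was each time the smallest the splits allow (0.0286, or 0.0667 without a WT and 0.1 without a KO library of the segment), and so says nothing about stability. With a preset correlation 14 lists passed in colon, 18 in cecum, 15 in ileum and 9 in jejunum. DESeq2 called 415 genes higher and 156 lower in ileum, 93 and 33 in jejunum, and 502 higher in KO colon than in WT ileum. Without a filter on low counts the calls were 318 and 152 in ileum and 88 and 32 in jejunum. With all 28 libraries in 1 fit they were 489 and 349 in ileum, 42 and 11 in jejunum, and 464 and 936 for KO colon against WT ileum, with 1492 higher in WT jejunum than WT ileum and 546 lower in WT cecum than WT colon. The limma trend test on deposited values called 23 genes lower in ileum. A threshold of 2-fold left 981 genes higher in KO cecum and 430 higher in WT cecum than WT colon, by construction. For the other settings the cause was not tested.

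With the replicate number as a block, 0 lists passed in colon and 0 in cecum by camera, against 6 and 5, and edgeR called 659 and 388 genes in ileum and 281 and 113 in jejunum. The other counts stayed within 1.5 times, among them the genes whose knockout effect differed from that in colon (820 for cecum, 646 for ileum and 749 for jejunum) and those shared by colon and cecum (1027). Of the named values only Per3 in cecum did not pass. The labels give no pairing. WT and KO libraries of 1 number correlated at -0.17 to 0.44 in their deviations, 7 of 12 above 0.1, and segments of 1 genotype and number at -0.056 to 0.49, 26 of 42 above 0.1, with all 4 above it for KO ileum and KO jejunum. Not every sample correlated best with its own number, but 5 of 12 did between genotypes and 29 of 42 between segments. Without pairing about 1 in 4 would do so between genotypes, and 1 in 3 WT or 1 in 4 KO between segments. The count between segments is a hint from the data, not the design, that a number may mark 1 animal across segments. The splits treat libraries as independent and would not hold then for comparisons between segments.

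Leaving out 1 library gave 0 to 6 lists past in colon and 866 to 1450 genes higher in KO cecum. In ileum 21 to 162 were higher and 10 to 68 lower, and in jejunum 8 to 45 and 2 to 12. WT ileum against WT colon gave 740 to 2039 higher and 707 to 1601 lower, WT jejunum against WT ileum 430 to 1173 and 303 to 1371, WT cecum against WT colon 395 to 765 and 505 to 802, and KO colon against WT ileum 140 to 557 and 319 to 850. Genes whose knockout effect differed between colon and cecum numbered 401 to 593. Part of the lower counts follows from fewer libraries.

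Of 196 named values past the test, all were run with RLE scaling and without a filter, 195 with DESeq2, 185 with all 28 libraries in 1 fit and with limma, and 135 on recovered reads. Each kept its direction there, and only Dbp and Nr1d1 in colon did not pass, in the fit of all 28. Many were named for large folds or small p-values in these same libraries, so this is in part built in. Without 1 library 23 of 1412 fits ended a call, in ileum (Rbp2, Sis, Slc2a5, Treh and Gbp2), jejunum (Tmprss15, Pdk4, Ces1d and Mt2), colon (Dbp) and cecum (Per3). Satb2 in jejunum, not past the test, turned from -0.12 to 0.0498 without WT jejunum library 2, in a range of -0.323 to 0.0498 over the libraries left out. The test recovered 9% of 2-fold changes in simulated ileum libraries and 82% of 4-fold ones. The spread was also largest there (biological coefficient of variation 32.9% against 24.7% in colon), so depth and spread were not separated.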

Other observations

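The splits of the libraries and the clock gene test were set before their results were seen, and the genes described together here were chosen after their values were seen. Genes that differ between WT cecum and WT colon were among those that changed in the knockouts. The mucin gene Muc2 was at 388 CPM in WT cecum and 6701 CPM in WT colon, and stood at 1280 CPM in KO cecum and 1540 CPM in KO colon. The sialyltransferase gene St3gal4, lower in WT cecum than in WT colon by 7.63 ± 0.421 (log2), rose by 9.18 in KO cecum and changed by 2.12 in KO colon. Reg4 was higher in WT cecum than in WT colon by 6.12 ± 0.383 and rose in KO colon by 6.17 ± 0.602. The transcription factor genes Creb3l3 and Pparg moved the same way in both knockouts, by 6.77 and -1.92 in colon and 4.39 and -2.45 in cecum.

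Slc16a9 and Slc37a2, for transporters of monocarboxylates and of sugar phosphates, were lost from a large-intestine knockout and gained in the jejunum knockout. Slc16a9 had no count in KO colon or KO cecum and stood at 44.8 and 85.3 CPM in their WT libraries, and in KO jejunum it was at 48.3 CPM against 0.234 in WT. Slc37a2 fell from 2950 to 0.438 CPM in KO cecum and rose in KO jejunum from 0.794 to 14.1 CPM.

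Other splits of the libraries show whether other labels give as many genes past the test. For KO against WT none did in colon (1743 genes, the highest other split 1), cecum (3280, other 1), ileum (146, other 1) or jejunum (30, other 2), each over 35 splits. The same held for the lists past the test in colon (6, other 1) and cecum (5, other 2), but without 1 library the count of lists in colon was 0 to 6. The real split is then 1 of 35, a share of 0.0286, the smallest these splits allow. This argues against chance but does not exclude it, and the splits treat the libraries as independent. For KO colon against WT ileum (867 genes, 35 splits) the highest other split gave 630. It exchanged only WT ileum library 3 and KO colon library 1, and so kept most of the real labels. The real split was again the highest of the 35, but a count near its own arose with wrong labels. Chance is not excluded there either. The 998 genes shared by colon and cecum (highest other split 0, of 100) add nothing to this, since no other split called more than 1 gene in either segment. The 10 splits of 6 WT libraries are too few to give a share under 0.05. They gave 2554 genes for ileum against colon, 1910 for jejunum against ileum and 1583 for cecum against colon. The highest other split gave 0 by edgeR in each.

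The clock gene contrast was also computed in the other segments. It was 0.988 ± 0.507 (log2, KO minus WT) in ileum (exact permutation p = 0.0857, two-sided), -1.25 ± 0.382 in cecum (exact permutation p = 0.0571) and -0.588 ± 0.384 in colon (exact permutation p = 0.314), and none passed after adjustment over the 4 segments (adjusted p from 0.171 to 0.314 for these 3). With 35 splits a single segment could reach an adjusted p of 0.114 at best, so no segment could pass on its own.

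Single clock genes, picked out after their values were seen, passed the test in cecum and colon. In KO cecum 4 evening genes were lower: Dbp (log2 fold change -3.62, adjusted p = 0.000764), Nr1d2 (-1.54, adjusted p = 0.000504), Nr1d1 (-1.36, adjusted p = 0.00749) and Per3 (-1.36, adjusted p = 0.0193, but 0.11 without WT cecum library 1, at -1.12). In KO colon the evening gene Nr1d1 (-0.92, adjusted p = 0.00592) was lower and the evening gene Per2 (1.43, adjusted p = 0.00656) and the morning gene Cry1 (1.24, adjusted p = 0.00582) were higher. Dbp fell in KO colon by 1.31 (adjusted p = 0.0434), but its adjusted p was above 0.05 in 6 of 7 fits without 1 library, up to 0.149, at -1.49 to -1.02, and 0.0728 (-1.30) with all 28 libraries in 1 fit, where that of Nr1d1 was 0.0624 (-0.90). No clock gene passed in ileum or jejunum. Adjusted over the clock list alone, 6 of 14 passed in jejunum, 5 of 13 in ileum, 4 of 13 in cecum and 4 of 13 in colon.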
